A study of Bos taurus with 12 samples.

How the data were processed

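RNA from 12 pools of cattle embryos had been measured on Affymetrix bovine arrays, 3 arrays in each of 4 groups: Day 7 blastocysts produced in vivo or in vitro, and Day 13 conceptuses grown in recipient heifers from blastocysts of either origin. Each Day 7 pool held 25 blastocysts and each Day 13 pool held 5 conceptuses, and 10 blastocysts had been placed in each recipient. The labels give 75 ng of total RNA per array, labelled with an Affymetrix protocol of 2 amplification cycles. The deposited values are log2 probe set intensities that the authors had normalized between arrays. The processing notes name RMA, GCRMA and limma without versions and without saying which of the first pair made the values. All arrays share a common floor and nearly equal distributions.

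The table held 24128 probe sets. The 112 control probe sets were left out of the tests and used as measures of each array, which left 24016. Of these, 13292 carried exactly 1 gene symbol and 10724 did not. The 9155 symbols were each represented by their probe set with the highest mean over the 12 arrays. The files hold no detection calls. A background of 3.39 on the log2 scale was therefore taken from the 99th percentile of 48 control probe sets that match no added RNA, a choice made after the data were seen. By it, 11653 probe sets stayed at background on all arrays and 10591 exceeded it on at least 3. Where every array of a group lay at background, the fold is given as a lower bound computed from the background, with the words "at least". For the difference of the day effect, groups wholly at background were set to the background. An adjusted p beside such a bound or difference is that of the fit to the deposited values. For arrays the number of pools limits the precision, and no read depth applies.

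A linear model with 4 group means was fitted to the deposited log2 values with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, with no replicate term. The 5 contrasts were Day 13 against Day 7 for each origin, in vitro against in vivo at each day, and the difference of the day effect between the origins. Probe sets were called at a Benjamini-Hochberg adjusted p below 0.05 over all those tested, and all tests were two-sided. The fit had 8 residual and 0.379 prior degrees of freedom. Errors given with differences are standard errors (SE) from this fit, and errors given with group levels are standard deviations (SD, n = 3). Effects shared between contrasts that use no array in common were counted as probe sets called in the same direction in both, beside the count expected for independent lists.

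Gene groups came from 34 lists of lineage markers, pathways, stress responses and other cell types, written with 1054 entries before the data were examined, of which 804 were measured. The 33 lists with at least 5 measured members were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists. Counts of members called over all probe sets stand beside counts adjusted over the list alone. The same test with a correlation estimated from the data, and fry, were run as alternatives. A range given beside a list is the lowest and the highest adjusted p over its alternatives. Named genes followed a rule also fixed before the data were examined: in each contrast the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap and whose brighter group exceeded the median of all probe sets, placeholder symbols left out (4 and 4, without the overlap condition, for the difference of the day effect), up to 4 members with the smallest adjusted p of each list described, and a fixed set of embryo genes. That set included NANOG, CDX2, GATA3 and SOX17, for which no probe set carried the symbol alone. PAPOLA and DKK3, and BEX4 in the day contrasts, were named after their values were seen.

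The same replicate number on arrays of different groups was tested as a pairing. After removal of group means, 3 of 18 same-numbered pairs of arrays correlated above 0.1, with a median r of -0.06, and 0 arrays correlated best with their own number in every other group, so no pairing was used and a replicate term was tried only as an alternative. Single pairs did correlate: same-numbered ones ran from -0.647 to 0.425. Day 7 in vitro replicate 3 and Day 13 in vivo replicate 2 reached 0.586. Such variation shared across groups was not modelled. The labels give no batch, and dates are not used here. The tests were tested on simulated data: over the 5 contrasts a log2 change of 4 was recovered in 66.7% to 87.9% of the changed probe sets and a change of 1 in 1.49% to 10.4%, and 6 to 12 unchanged probe sets of 24016 were called. The simulated noise was independent between probe sets and between arrays, and only probe sets of middle brightness were changed. These rates therefore do not show how the tests behave with variation shared across an array, or near background.

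The alternatives chosen in advance were quantile normalization again, centring of each array on its median or on the ribosomal protein genes, filters on dim probe sets, trended and robust variance, array quality weights, fits with only the groups compared, a replicate term, leaving out each array, stricter thresholds, and genes in place of probe sets. Alternatives chosen after seeing the data were leaving out Day 13 in vitro arrays 1 and 2 together, covariates for the poly-A spike-ins and for the GAPDH 3' minus 5' difference, a filter on background, and further versions of the array weights. The closing section gives their effect.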

Results

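The data describe cattle embryos on either side of the start of elongation. There were 12 pools, 3 in each of 4 groups: Day 7 blastocysts made in vivo, Day 7 blastocysts made in vitro, and Day 13 conceptuses recovered from recipient heifers after transfer of blastocysts of each origin. Between 41.3% and 42.0% of the 24016 probe sets exceeded background on each array. Replicate arrays correlated at r = 0.963 to 0.991 across probe sets, which are not independent replicates. Arrays of different origin could correlate as well. Day 13 in vitro replicate 3 reached 0.968 and 0.977 with its own replicates 1 and 2. With Day 13 in vivo replicates 1, 2 and 3 it reached 0.980, 0.960 and 0.981. Day 7 in vitro replicate 2 reached 0.988 and 0.978 with in vitro replicates 1 and 3, and 0.986 with in vivo replicate 2. The first principal component held 47.8% of the variance, with Day 7 arrays from -73.0 to -48.3, Day 13 in vivo arrays from 22.2 to 32.3 and Day 13 in vitro arrays from 60.5 to 117.

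Control probe sets differed between groups. The poly-A spike-ins, added to the RNA before labelling, averaged 14.7 ± 0.44 (SD, n = 3) in Day 7 in vivo arrays, 14.1 ± 0.64 in Day 7 in vitro, 14.5 ± 0.17 in Day 13 in vivo and 11.01 ± 1.87 in Day 13 in vitro, where replicates 1, 2 and 3 lay at 9.38, 10.61 and 13.06. The hybridization spike-ins were 13.2 ± 0.36, 12.5 ± 0.52, 13.2 ± 0.27 and 11.4 ± 0.79 in the same order of groups. The 3' minus 5' difference of GAPDH, a measure of how far labelling reached along the transcript, was 5.61 ± 0.04, 3.69 ± 0.43, 4.01 ± 1.01 and 3.10 ± 0.92. That of cyclophilin was 4.86 ± 0.28, 4.33 ± 0.25, 4.36 ± 0.18 and 3.92 ± 0.57.

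**Figure D1:**
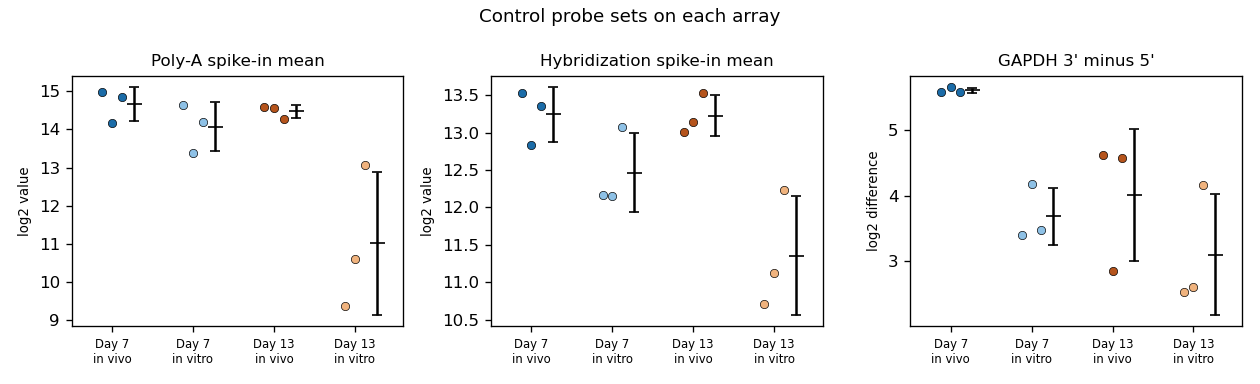
Control measures on each of the 12 arrays: log2 means of the poly-A and hybridization spike-ins and the log2 difference between GAPDH 3' and 5' probe sets. Points are arrays, and bars are the mean and SD of 3 arrays; Day 13 in vitro replicates 1 and 2 have the lowest poly-A values, 9.38 and 10.61.

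The first question was how the transcriptome of embryos made in vivo changed from blastocyst to Day 13 conceptus. DNASE1L3, a secreted DNA-cutting enzyme, was at least 475-fold higher at Day 13 (adjusted p = 2.66e-06), and the gap junction protein gene GJA1 rose by 9.02 ± 0.38 (log2 difference ± SE, adjusted p = 1.2e-05). TKDP1, a secreted trophoblast protein, rose by 7.61 ± 1.02 (adjusted p = 0.00508). The keratin gene KRT5 fell by 5.88 ± 0.44 (adjusted p = 0.000236), and the kinase gene ZAP70 fell by 6.45 ± 0.18 (adjusted p = 1.06e-06). In total 911 of 24016 probe sets passed, 408 higher and 503 lower at Day 13, for 503 named genes.

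Among the other largest rises, the sulfate transporter gene SLC13A4 rose by 7.14 ± 0.59 and the co-chaperone gene BAG3 by 6.64 ± 1.08. KLB, a co-receptor for fibroblast growth factors, was at least 64.3-fold higher, the activin-binding protein gene FST at least 79.4-fold and PRSS35 at least 41.0-fold. Among the falls, EFHD1 fell by 6.63 ± 0.21, the galectin gene LGALS4 fell by 6.42 ± 0.67, the antibody receptor gene FCGR2B fell by 6.23 ± 0.40, the tight junction gene CLDN10 fell by 5.95 ± 0.48 and AIF1L fell by 5.78 ± 0.30. STAT3 was at least 50.5-fold lower by its brightest probe set, while its other probe set above background did not pass. For each gene named by the size of its change, the arrays of the groups compared did not overlap. BEX4 rose by 5.96 ± 0.68 (adjusted p = 0.00235) and DKK3 was at least 6.87-fold higher (adjusted p = 0.0028); both are named for their opposite course in embryos made in vitro.

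Trophoblast identity genes included 4 higher and 0 lower of 19 measured (5 higher when adjusted over the list alone), with ASCL2 up by 3.84 ± 0.25, KRT19 by 4.56 ± 0.69 and SSLP1 by 3.17 ± 0.50. The list itself did not pass (camera adjusted p = 0.0706). Secreted trophoblast products included 4 higher of 26, among them PAG8 (at least 36.0-fold) and TKDP4 (at least 10.96-fold), with a camera adjusted p of 0.151. Hypoblast and yolk sac genes included 6 higher and 1 lower of 30 (camera adjusted p = 0.071). The laminin gene LAMB1 rose by 2.85 ± 0.35, NID2 by 2.19 ± 0.31 and the apolipoprotein gene APOE by 4.05 ± 0.60, and APOA2 was at least 28.1-fold higher. Of 9 pluripotency genes 1 rose, the NODAL co-receptor gene CRIPTO (4.85 ± 0.27), and 1 fell, STAT3. POU5F1 differed by -1.64 ± 0.76 (adjusted p = 0.403). Junction and pump genes included 5 higher and 2 lower of 23 (camera adjusted p = 0.651). SLC9A3 rose by 4.18 ± 0.38. Of 25 imprinted genes, 3 were higher and 1 lower (camera adjusted p = 0.255). PEG3 rose by 2.85 ± 0.53 and NDN fell by 3.17 ± 0.59.

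Cholesterol biosynthesis genes rose together: 7 of 17 were higher and 0 lower (11 higher adjusted over the list alone), with a median log2 difference of 1.31 (camera adjusted p = 3.38e-07). CYP51A1 rose by 3.40 ± 0.46, SQLE by 2.65 ± 0.37 and MSMO1 by 1.69 ± 0.24. With an estimated correlation the list had an adjusted p = 0.0477, the highest of its 14 alternatives (range 1.39e-07 to 0.0477). Heat shock and unfolded protein response genes included 4 higher of 27 (11 over the list alone; camera adjusted p = 9.25e-07, estimated correlation adjusted p = 0.354, range 5.65e-09 to 0.354), with HSPA5 up by 1.49 ± 0.18, HERPUD1 by 2.90 ± 0.35 and PDIA4 by 3.94 ± 0.62. Ribosomal protein genes included 3 higher of 62, with a median of 0.46, or 0.24 with quantile normalization (camera adjusted p = 7.53e-10, estimated correlation adjusted p = 0.513, range 1.19e-12 to 0.513). RPS20 rose by 1.03 ± 0.17. Hypoxia response genes went both ways, 4 higher and 2 lower of 18 (camera adjusted p = 0.604). PLOD2 rose by 6.02 ± 0.39, EPAS1 by 2.58 ± 0.41 and BNIP3L changed by -2.12 ± 0.25. The GAPDH 3' minus 5' difference was 5.61 at Day 7 and 4.01 at Day 13 in these embryos. Glycolysis genes included 3 higher of 20 (camera adjusted p = 0.0139, estimated correlation adjusted p = 0.552, range 0.00183 to 0.966). TPI1 rose by 5.78 ± 0.87 and PFKFB3 by 3.93 ± 0.64. With the GAPDH difference as a covariate the list's direction turned (adjusted p = 0.966), though GAPDH is itself a glycolysis gene. Oxidative stress genes included 3 higher of 28 (camera adjusted p = 0.0301, estimated correlation adjusted p = 0.513, range 0.00465 to 0.513), with TXN up by 1.11 ± 0.15 and SOD1 by 2.79 ± 0.40. The list's median was 0.27, and -0.14 when arrays were centred on ribosomal protein genes.

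Fitting only the 6 arrays of these groups called 241 probe sets, and centring on ribosomal protein genes, which shifts the median of all probe sets by -0.41, called 1627 with 23.0% higher in place of 44.8%. Without a Day 13 array the share was 52.3% to 55.6%. In all, 17 of the 70 named calls were lost without at least 1 of the 6 arrays. The glycolysis call was lost without Day 13 in vivo replicate 2 (adjusted p = 0.13). The oxidative stress call was lost without Day 7 replicate 1 or 2 or Day 13 replicate 2 or 3 (adjusted p up to 0.0791). The calls of PEG3 (adjusted p up to 0.0681) and NDN (up to 0.0722) were lost without Day 7 replicate 1 or 2 or Day 13 replicate 2, that of PEG3 also without Day 13 replicate 3, and that of NDN also without Day 7 replicate 3 or Day 13 replicate 1.

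The same question for embryos made in vitro gave 1804 probe sets, 852 higher and 952 lower at Day 13, for 986 named genes. DNASE1L3 rose by 10.67 ± 0.33 (adjusted p = 1.7e-06) and TKDP1 by 8.17 ± 1.02 (adjusted p = 0.00245). The pregnancy-associated glycoprotein genes PAG11 and PAG8, products of ruminant trophoblast, were at least 313-fold and at least 93.7-fold higher. The surface protein gene CD48 was at least 497-fold lower (adjusted p = 1.7e-06), KRT5 fell by 8.43 ± 0.44 (adjusted p = 3.07e-05), and the pluripotency factor gene POU5F1 fell by 5.80 ± 0.76 (adjusted p = 0.00317).

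Other large rises were those of PDZK1 (at least 114-fold), the homeobox gene IRX3 (7.24 ± 0.51), CRIPTO (at least 99.8-fold) and ARHGDIB (at least 57.3-fold). Other large falls were those of LGALS4 (-8.31 ± 0.67), TRIB2 (-7.67 ± 0.51) and the transcription factor gene KLF13 (-6.77 ± 0.77), while ZAP70 was at least 110-fold lower, GNMT at least 132-fold and AIF1L at least 57.9-fold. BEX4 fell by 2.94 ± 0.68 (adjusted p = 0.0361) and DKK3 was at least 2.37-fold lower (adjusted p = 0.0182). Each of these calls was lost without Day 7 in vitro replicate 1 or 3 or Day 13 in vitro replicate 1 or 2, with adjusted p up to 0.134 and 0.0749. The interferon tau gene IFNT2, the signal of pregnancy recognition in ruminants, differed by 1.96 ± 0.84 (adjusted p = 0.253), the prostaglandin synthase gene PTGS2 by 0.91 ± 0.52 (adjusted p = 0.448) and PAG2 by -0.997 ± 0.82 (adjusted p = 0.68). The endoderm factor gene GATA6 fell by 1.81 ± 0.42 (adjusted p = 0.0365), a call lost when any 1 of the 6 arrays, Day 7 or Day 13 in vitro replicates 1, 2 and 3, was left out (adjusted p up to 0.128).

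**Figure D2:**
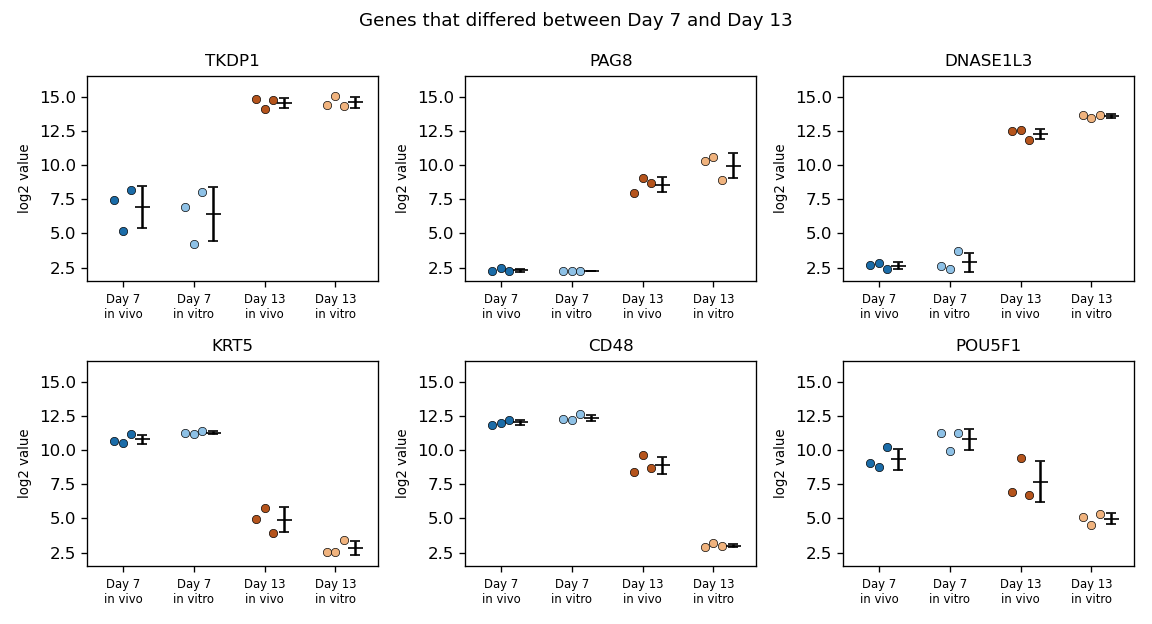
Log2 values of TKDP1, PAG8, DNASE1L3, KRT5, CD48 and POU5F1 on each of the 12 arrays. Points are arrays, and bars are the mean and SD of 3 arrays in each group; CD48 was 8.89 ± 0.63 in Day 13 in vivo and 3.02 ± 0.14 in Day 13 in vitro conceptuses.

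Trophoblast identity genes included 7 higher and 1 lower of 19 (camera adjusted p = 0.0119, estimated correlation adjusted p = 0.433, range 4.1e-05 to 0.433). ASCL2 rose by 4.58 ± 0.25, SSLP1 by 6.01 ± 0.50 and ERRFI1 by 1.33 ± 0.20, and ELF5 was at least 4.21-fold higher. Secreted trophoblast products included 5 higher of 26 (camera adjusted p = 0.033, estimated correlation adjusted p = 0.433, range 0.000644 to 0.433). TKDP4 was at least 30.9-fold higher. The list's median was 0, or -0.0135 with arrays centred on their medians, and its mean 1.42. Heat shock and unfolded protein response genes included 10 higher and 1 lower of 27 (14 and 1 over the list alone; camera adjusted p = 2.46e-05, estimated correlation adjusted p = 0.433, range 8.61e-06 to 0.433). HERPUD1 rose by 3.94 ± 0.35, HSPH1 by 3.40 ± 0.38 and HSPD1 by 0.97 ± 0.15. Ribosome biogenesis genes included 4 higher of 28 (camera adjusted p = 0.0029, estimated correlation adjusted p = 0.583, range 0.000401 to 0.583). DDX21 rose by 1.67 ± 0.19. Cell cycle genes included 4 higher of 44 (camera adjusted p = 0.0119, estimated correlation adjusted p = 0.583, range 0.00475 to 0.747). CDC6 rose by 3.14 ± 0.33 and PCNA by 1.504 ± 0.24. The Day 13 in vitro arrays with the lowest poly-A spike-in values were among those compared, and with the spike-in mean as a covariate the cell cycle list had an adjusted p = 0.747, the highest of its 15 alternatives.

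Oxidative phosphorylation genes were lower as a list (camera adjusted p = 0.0119, estimated correlation adjusted p = 0.835, range 2.3e-06 to 0.835), with a median of -0.36, or -0.19 when arrays were centred on ribosomal protein genes, 1 higher and 4 lower of 69. COX5B fell by 0.63 ± 0.11, a call lost without Day 7 replicate 3 or Day 13 replicate 1 or 2 (adjusted p up to 0.0579), whereas NDUFB2 rose by 0.99 ± 0.17 by its brightest probe set and was -1.22 by its other one. Cholesterol biosynthesis genes had a median of -0.47, or -0.29 with that centring, with 0 higher and 1 lower of 17, FDFT1, which fell by 1.75 ± 0.30 (camera adjusted p = 0.0339, estimated correlation adjusted p = 0.433, range 0.0131 to 0.433). Cytoskeleton and adhesion genes included 2 higher and 4 lower of 36 (camera adjusted p = 0.64). TPM1 fell by 2.98 ± 0.24 and ACTN1 fell by 3.22 ± 0.33. Lipid genes included 3 higher and 4 lower of 41 (camera adjusted p = 0.825), with AGPAT3 up by 4.69 ± 0.22 and the lipid droplet gene PLIN2 at -2.79 ± 0.26. Oxidative stress genes included 4 higher and 1 lower of 28 (camera adjusted p = 0.139), with MGST1 up by 4.28 ± 0.53. Growth factor genes included 2 higher and 1 lower of 44 (camera adjusted p = 0.963), with AREG at least 9.88-fold higher.

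The count was 913 without Day 7 in vitro replicate 1, 1001 without replicate 3, and 961, 967 and 2898 without Day 13 in vitro replicates 1, 2 and 3. Without Day 13 replicates 1 and 2 together it was 902, of which 469 were among the 1804 and 70.3% were higher, in place of 47.2%. Without Day 13 replicate 3 the share higher was 56.5%, and with arrays centred on ribosomal protein genes 56.9%. With the poly-A covariate it was 199, and that fit kept 26 of the 74 named calls. Leaving out single arrays lost 19 of those 74 calls at least once. Without Day 13 in vitro replicate 3 the calls of trophoblast identity, secreted products, oxidative phosphorylation and cholesterol biosynthesis were lost (highest adjusted p 0.101, 0.0681, 0.086 and 0.0817 over the arrays left out). Those of secreted products and cholesterol were also lost without Day 7 replicate 1, that of cholesterol without Day 7 replicate 2 or Day 13 replicate 2, and that of oxidative phosphorylation without Day 7 replicate 3.

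The next question was whether blastocysts of the 2 origins differed before transfer. Cholesterol biosynthesis genes were higher in those made in vitro. The mean of the 15 list members above background was 9.49 ± 0.15 (SD, n = 3) in vitro and 7.68 ± 0.03 in vivo, and every in vitro array lay above every in vivo array. CYP51A1 was higher by 3.72 ± 0.46 (adjusted p = 0.0252), HMGCS1 by 2.38 ± 0.29 (adjusted p = 0.0252), FDFT1 by 2.33 ± 0.30 (adjusted p = 0.0292) and MSMO1 by 1.76 ± 0.24 (adjusted p = 0.0412). In all, 50 probe sets passed, 31 higher and 19 lower in vitro, for 27 named genes. Of the 17196 probe sets that varied on these arrays, 13.0% had groups that did not overlap, where chance gives 10%. That share was 19.9% and 32.3% in the day comparisons, in vivo and in vitro, and 21.0% between the origins at Day 13.

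The cholesterol list included 4 higher and 0 lower of 17 (11 higher adjusted over the list alone), with a median log2 difference of 1.76 and a camera adjusted p of 4.17e-14. With an estimated correlation its adjusted p = 0.005, the highest of 14 alternatives (range 7.45e-16 to 0.005), all of which it passed. Its median was 1.28 when arrays were centred on ribosomal protein genes. The call of CYP51A1 was lost without Day 7 in vitro replicate 1 (adjusted p = 0.0886). Those of HMGCS1, FDFT1 and MSMO1 were lost without that array or Day 7 in vivo replicate 1 (adjusted p up to 0.0834, 0.093 and 0.155). That of FDFT1 was also lost without Day 7 in vivo replicate 3, and that of MSMO1 without replicate 2 of either origin.

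**Figure D3:**
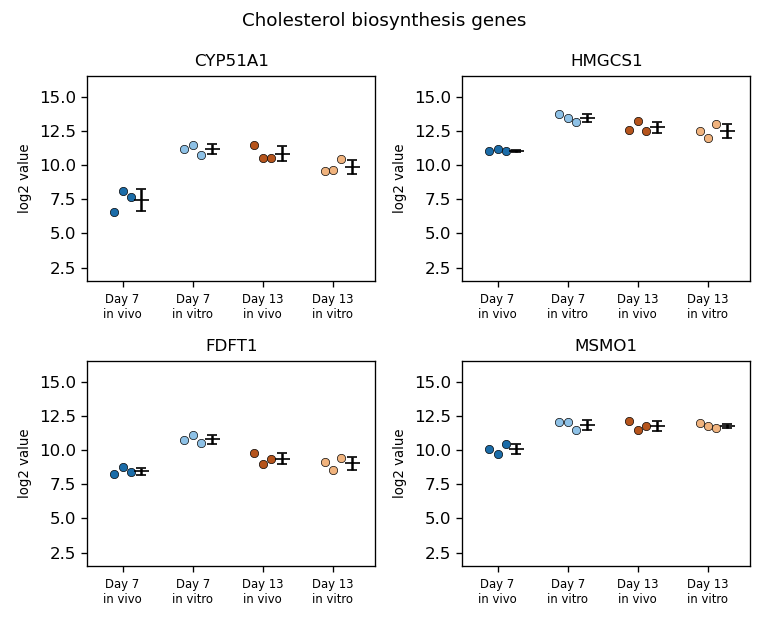
Log2 values of CYP51A1, HMGCS1, FDFT1 and MSMO1, enzymes of cholesterol biosynthesis, on each of the 12 arrays. Points are arrays, and bars are the mean and SD of 3 arrays in each group; CYP51A1 was 7.43 ± 0.80 in Day 7 in vivo and 11.14 ± 0.37 in Day 7 in vitro blastocysts.

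Outside this list, FMR1NB was at least 7.27-fold higher in vitro (adjusted p = 0.0159) and the germline gene MAEL was higher by 3.18 ± 0.22 (adjusted p = 0.00143). The nitric oxide synthase gene NOS2 was higher by 2.89 ± 0.36, GJA1 by 2.83 ± 0.38 and the basement membrane gene NID2 by 2.69 ± 0.31. PLOD2, a collagen-modifying enzyme, was higher by 3.15 ± 0.39 by its brightest probe set and near 0 by its other one (-0.000946). CRIPTO was at least 8.46-fold lower in vitro (adjusted p = 0.00257), FCGR2B was lower, at -3.64 ± 0.40 (adjusted p = 0.0159), and AASS, of lysine breakdown, at -2.04 ± 0.19 (adjusted p = 0.00562). SLC28A3 was at least 1.23-fold lower. The calls of FMR1NB, NOS2, GJA1, PLOD2, SLC28A3 and NDUFB2 were lost without Day 7 in vitro replicate 1 (highest adjusted p over the arrays left out 0.0533, 0.0776, 0.102, 0.089, 0.12 and 0.135). All but that of FMR1NB were also lost without in vivo replicate 1, those of GJA1 and NDUFB2 also without in vitro replicate 2 or 3 or in vivo replicate 2. Those of NOS2 and PLOD2 were lost without in vivo replicate 3, and that of SLC28A3 without in vitro replicate 3. CPT1B and MTFR1 passed at background in both groups, and NDUFB2 was -1.23 ± 0.17 by its brightest probe set and 0.79 by its other one. IFNT2 (0.18 ± 0.84), PTGS2 (-0.58 ± 0.52), POU5F1 (1.45 ± 0.76) and GATA6 (-0.04 ± 0.42) did not pass (adjusted p of 0.836 or more).

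Further lists were higher in vitro by camera, and the GAPDH 3' minus 5' difference, 5.61 ± 0.04 in vivo and 3.69 ± 0.43 in vitro, separated the same groups. That of cyclophilin, 4.86 ± 0.28 and 4.33 ± 0.25, overlapped between them, with in vivo replicate 1 at 4.54 and in vitro replicate 3 at 4.62. Hypoxia response genes had a median of 0.83 with 1 higher of 18 (6 over the list alone; camera adjusted p = 5e-07, estimated correlation adjusted p = 0.0728, range 1.31e-09 to 0.0728). PLOD2 passed, and VEGFA was 2.22 ± 0.39 (adjusted p = 0.1). Glycolysis genes had a median of 0.93 with 0 of 20 called (5 over the list alone; camera adjusted p = 3.39e-06, estimated correlation adjusted p = 0.358, range 3.21e-07 to 0.812). Oxidative phosphorylation genes had a median of 0.57 with 0 higher and 1 lower of 69 (camera adjusted p = 9.27e-08, estimated correlation adjusted p = 0.559, range 1.64e-08 to 0.559). With the GAPDH difference as a covariate the direction of these last lists turned (adjusted p = 0.812 and 0.0675). GAPDH is itself a glycolysis gene, at 10.9 to 12.1 in vivo and 12.8 to 13.4 in vitro, so this covariate is not independent of that list. Ribosomal protein genes had a median of 0.48 with 0 of 62 called (3 over the list alone; camera adjusted p = 1.66e-18, estimated correlation adjusted p = 0.358, range 6.75e-19 to 0.358). Heat shock genes had a median of 0.55 with 0 of 27 called (camera adjusted p = 0.00166, estimated correlation adjusted p = 0.358, range 4.96e-06 to 0.472). Oxidative stress genes had 1 higher of 28, TXN at 1.09 ± 0.15, a call lost when any 1 of the arrays but in vivo replicate 3 was left out (adjusted p up to 0.124; list camera adjusted p = 0.00458, estimated correlation adjusted p = 0.358, range 0.000549 to 0.812). Lipid genes had 0 of 41 called (camera adjusted p = 0.0401, estimated correlation adjusted p = 0.163, range 0.0306 to 0.584). Centring arrays on ribosomal protein genes took the medians of hypoxia, glycolysis, oxidative phosphorylation, heat shock and ribosomal protein genes to 0.36, 0.45, 0.09, 0.08 and 0.00840. The last value follows from the centring itself and is no test of the ribosomal list. The same centring turned the medians of oxidative stress and lipid genes from 0.24 and 0.15 to -0.24 and -0.32. With quantile normalization those of ribosomal protein and lipid genes were 0.24 and 0.07. Cumulus and granulosa markers, in contrast, were lower in vitro as a list, with 0 of 15 called (camera adjusted p = 0.0221, estimated correlation adjusted p = 0.163, range 0.00592 to 0.192) and a median of -0.04, or 0.02 when arrays were centred on their medians and -0.51 when centred on ribosomal protein genes. Only 3 members lay above background on all arrays of a Day 7 group, and HAS2 (-0.75 ± 0.21, adjusted p = 0.422), STAR (-1.11) and HSD3B1 (0.41) went both ways.

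The fit with only these 6 arrays called 3 probe sets, and the count was 111 without Day 7 in vitro replicate 2 and 76, 116 and 101 without in vivo replicates 1, 2 and 3. Centring on ribosomal protein genes, which shifts the median of all probe sets by -0.48, left 28.0% of called probe sets higher in place of 62.0%, and quantile normalization 50%. Without an in vivo array the share was 30.7% to 35.3%, and without an in vitro array 75.6% to 82.0%. The balance of higher and lower calls therefore turned with the group that lost an array, whichever array it was. Of the 19 named calls 11 were lost without at least 1 array, and so were the list calls of heat shock (without in vivo replicate 1, adjusted p = 0.104), of cumulus markers (without in vitro replicate 1 or 2 or in vivo replicate 1, up to 0.104) and of lipid genes (when any 1 of the 6 arrays was left out, up to 0.0983).

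After growth in recipients, Day 13 conceptuses from blastocysts of each origin were compared. CD48 was at least 45.3-fold lower in conceptuses of in vitro origin (adjusted p = 9.89e-05) and the alcohol dehydrogenase gene ADH6 at least 26.3-fold lower (adjusted p = 2.94e-05). The complement factor gene CFI was at least 17.6-fold higher (adjusted p = 0.000833) and AREG, an epidermal growth factor receptor ligand, at least 9.88-fold higher (adjusted p = 0.00795). ADH6, CFI and AREG lay at background on every array of 3 of the 4 groups, where values hardly vary. Their adjusted p therefore says little of the spread in the remaining group. It ran from 7.44 to 8.48 for ADH6 (in vivo), 6.73 to 8.68 for CFI and 5.38 to 7.99 for AREG (both in vitro). The poly-A spike-ins lay at 14.5 ± 0.17 (SD, n = 3) in the in vivo and 11.01 ± 1.87 in the in vitro arrays of this comparison. XIST, the transcript of the inactive X chromosome, was -4.37 ± 1.51 (adjusted p = 0.214), and the sex of the conceptuses was not tested apart from their origin. In the 12-array fit 288 probe sets passed, 155 higher and 133 lower, for 150 named genes. In a fit with only these 6 arrays limma called 0, with 2178 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0596, and 0 of the 19 named calls passed.

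MGST1, a membrane-bound glutathione transferase, was higher by 4.47 ± 0.53 and the estrogen-forming enzyme gene HSD17B1 by 4.42 ± 0.73. FRRS1 was at least 10.8-fold higher, TMEM50B at least 11.05-fold, MICU3 at least 8.75-fold and ZMYM5 at least 12.1-fold. Among lower genes were ZBTB44 (-5.37 ± 0.70), BEX4 (-5.27 ± 0.68), TRIB2 (-5.08 ± 0.51), the apolipoprotein gene APOA2 (-4.97 ± 0.88) and BEX3 (-4.85 ± 0.81), and ANXA13 was at least 11.98-fold lower. IFNT2 was 12.2 ± 1.47 in conceptuses of in vitro and 9.13 ± 0.80 in those of in vivo origin, a difference of 3.08 ± 0.84 that did not pass (adjusted p = 0.13). POU5F1 (-2.71 ± 0.76, adjusted p = 0.139), PTGS2 (0.94 ± 0.52, adjusted p = 0.462) and TKDP1 (0.02 ± 1.02) did not pass either.

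Cell cycle genes were higher as a list in conceptuses of in vitro origin, with a median of 0.59, or 0.30 with quantile normalization, 1 higher of 44 (7 over the list alone) and a camera adjusted p of 0.000105 (estimated correlation adjusted p = 0.3, range 3.33e-05 to 0.528). The highest was with the poly-A covariate. CCNE2, a cyclin that acts at entry to DNA replication, passed at 2.52 ± 0.36 (adjusted p = 0.0188), and CDC6 was 1.46 ± 0.33 (adjusted p = 0.0794). Heat shock genes had a median of 0.45, or 0.27 with quantile normalization, with 0 of 27 called (5 higher and 1 lower over the list alone; camera adjusted p = 0.0196, estimated correlation adjusted p = 0.409, range 0.00246 to 0.409). Hypoblast and yolk sac genes were lower as a list, with 0 higher and 1 lower of 30, APOA2 (camera adjusted p = 0.0293, estimated correlation adjusted p = 0.237, range 0.00117 to 0.237). The median was -0.05, but 0.0142 when arrays were centred on their medians and 0.0649 when centred on ribosomal protein genes. COL4A1 was -2.22 ± 0.48 (adjusted p = 0.0698). Cumulus and granulosa markers included 0 higher and 1 lower of 15, the matrix protein gene TNFAIP6, at least 3.08-fold lower (camera adjusted p = 0.0293, estimated correlation adjusted p = 0.237, range 0.00117 to 0.237). Cholesterol biosynthesis genes had 0 of 17 called and a median of -0.26 (camera adjusted p = 0.146).

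The count was 135, 152 and 2058 without in vitro replicates 1, 2 and 3, 459 without replicates 1 and 2 together (91 of them among the 288, and 404 higher; the lone array is assumed to vary like the other groups) and 9 with the poly-A covariate, which kept CD48 and ADH6 of the named calls. Quantile normalization gave 43.4% higher in place of 53.8%, centring on ribosomal protein genes 63.4% and on medians 63.3%. With single arrays left out the share ran from 32.8% (without in vivo replicate 2) to 66.0% (without in vitro replicate 3). The list calls of hypoblast, cumulus and heat shock genes were lost without in vitro replicate 3 (highest adjusted p 0.105, 0.17 and 0.101 over the arrays left out). The first was also lost without in vivo replicate 1 and the other pair without in vivo replicate 3. In all, 8 of the 19 named calls were lost without at least 1 array. Without in vitro replicate 2 the calls of APOA2, BEX3, CCNE2, HSD17B1, TMEM50B, ZMYM5, FRRS1 and MICU3 were lost (highest adjusted p over the arrays left out 0.15, 0.128, 0.0778, 0.112, 0.121, 0.128, 0.0813 and 0.0836). The first 6 of these were also lost without in vitro replicate 1, and 5 of them, all but CCNE2, without in vivo replicate 1. Those of BEX3, TMEM50B, ZMYM5 and MICU3 were lost without in vivo replicate 2 or 3, and that of HSD17B1 without in vivo replicate 3.

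The direct test of whether the change from Day 7 to Day 13 depended on origin called 96 probe sets, 35 with a higher and 61 with a lower log2 change in vitro, for 47 named genes. The cholesterol list had the lower change in vitro, with a median of -1.94, 0 higher and 3 lower of 17 (10 lower over the list alone; camera adjusted p = 6.53e-10, estimated correlation adjusted p = 0.0169, range 1.72e-10 to 0.0169). CYP51A1 (-4.67 ± 0.64, adjusted p = 0.0274), HMGCS1 (-2.64 ± 0.41, adjusted p = 0.0476) and FDFT1 (-2.65 ± 0.42, adjusted p = 0.0488) passed, and SQLE was -3.21 ± 0.52 (adjusted p = 0.0532). CYP51A1 went from 7.43 to 10.83 in vivo and from 11.14 to 9.88 in vitro. The mean of the list members above background was lowest in Day 7 in vivo arrays, 7.68. It was 9.49 in Day 7 in vitro, 9.09 in Day 13 in vivo and 8.80 in Day 13 in vitro arrays. The rise in vivo, the Day 7 difference between origins and this result all use the Day 7 in vivo arrays, so they are not independent findings.

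BEX4, of a family of small adaptor proteins, rose in vivo and fell in vitro, a difference of -8.90 ± 0.97 (adjusted p = 0.00833). BEX3 (-7.48 ± 1.14, adjusted p = 0.045) also had the lower change in vitro and TMEM106C (2.58 ± 0.40, adjusted p = 0.0466) the higher. For the other genes named here whole groups lay at background, and the differences are given with the background in place of those groups. The adjusted p beside them belong to the differences fitted to the deposited values. Those were -6.21 for CD48, -5.51 for DKK3, -5.83 for ADH6, 5.26 for CFI, 3.32 for TMEM38B and 3.26 for SLC12A2. That of CD48, -5.84 (adjusted p = 0.000902), and that of DKK3, a secreted protein related to WNT inhibitors, -4.03 (adjusted p = 0.00671), are bounds, the true differences being as large or larger. Those of ADH6 (-4.72, adjusted p = 0.000512), CFI (4.14, adjusted p = 0.00833), TMEM38B (2.61, adjusted p = 0.0393) and the ion cotransporter gene SLC12A2 (3.69, adjusted p = 0.0125) have no bound, as 3, 3, 3 and 2 of their 4 groups lay at background. Ribosomal protein genes had the lower change as a list, with a median of -0.55 and 0 of 62 called (camera adjusted p = 8.72e-11, estimated correlation adjusted p = 0.593, range 6.32e-13 to 0.593). So did oxidative phosphorylation genes, with a median of -0.42 and 0 of 69 called (camera adjusted p = 0.0178, estimated correlation adjusted p = 0.851, range 5.57e-05 to 0.987). With arrays centred on ribosomal protein genes, which shifts the median of all probe sets by 0.59, these medians were 0.04 and 0.17. The first value follows from the centring itself and is no test of the ribosomal list. Cell cycle genes had the higher change, with a median of 0.43 (0.20 with quantile normalization and 1.02 with that centring) and 0 of 44 called (camera adjusted p = 0.00148, estimated correlation adjusted p = 0.485, range 9.75e-06 to 0.485). Ribosome biogenesis genes had a median of 0.19 (0.0129 and 0.78 in the same order) and 0 of 28 called (camera adjusted p = 0.0452, estimated correlation adjusted p = 0.593, range 0.00103 to 0.593). The GAPDH 3' minus 5' difference and the poly-A spike-ins differed between the same groups, and with the first as a covariate the oxidative phosphorylation list had an adjusted p = 0.987.

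The count was 1083 without Day 13 in vitro replicate 3, 147, 193 and 156 without Day 13 in vivo replicates 1, 2 and 3, and 424 without Day 13 in vitro replicates 1 and 2 together (59 of them among the 96). Centring on ribosomal protein genes gave 73.5% with the higher change in place of 36.5%, and leaving out single arrays from 22.8% to 63.2%, or 88.7% without Day 13 in vitro replicates 1 and 2. The calls of CYP51A1, HMGCS1, FDFT1, BEX3, TMEM38B and TMEM106C were lost without 5, 10, 10, 9, 9 and 10 of the 12 arrays (adjusted p up to 0.0822, 0.119, 0.118, 0.118, 0.103 and 0.103), each of them without Day 7 in vitro replicate 1, 2 or 3. The others were Day 13 in vitro replicates 1 and 2 for CYP51A1, every array but Day 13 in vitro replicate 3 and Day 13 in vivo replicate 2 for HMGCS1 and FDFT1. They were every array but Day 7 in vivo replicates 1 and 3 and Day 13 in vitro replicate 3 for BEX3, every array but the Day 13 in vitro ones for TMEM38B and every array but Day 13 in vitro replicates 1 and 3 for TMEM106C. The call of oxidative phosphorylation was lost without Day 7 in vitro replicate 3, Day 13 in vitro replicate 3 or Day 13 in vivo replicate 2 (up to 0.356). That of ribosome biogenesis was lost without Day 7 in vitro replicate 2, Day 7 in vivo replicate 1 or 3, Day 13 in vitro replicate 1 or 3 or Day 13 in vivo replicate 1 or 3 (up to 0.355).

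The day effect was partly common to both origins: 462 probe sets passed in the same direction in both, 180 higher and 282 lower, another 446 in vivo alone and 1339 in vitro alone. Of those called in vivo 90.1% had the same sign in vitro, and of those called in vitro 88.4% in vivo. For independent lists 14.5 and 19.9 were expected over all probe sets, or 30.3 and 42.5 over the 10591 above background, as dim probe sets can hardly pass. A further 3 passed in opposite directions, BEX4, DKK3 and a probe set without a name. Across these 10591 the log2 changes correlated with r = 0.583 and rho = 0.473, though probe sets are not independent replicates. DNASE1L3, TKDP1, ASCL2, GJA1 and PAG8 rose and KRT5, ZAP70, LGALS4 and AIF1L were lower at Day 13 in both. For the origin difference 1 probe set passed in the same direction at both days. Over all probe sets 0.2 were expected higher and 0.105 lower, or 0.402 and 0.136 over the 10591 above background. The correlation was r = 0.0567 and rho = 0.0522. By camera, heat shock genes were higher and cumulus markers lower in vitro at both days, calls lost with an estimated correlation (adjusted p = 0.358 and 0.409, 0.163 and 0.237, with the ranges given above). The probe set was for PAPOLA, a poly-A polymerase, higher in vitro by 1.12 ± 0.11 at Day 7 (adjusted p = 0.0122) and by 1.09 ± 0.11 at Day 13 (adjusted p = 0.00456), and named after its values were seen. This count was 0 with a replicate term, with trended variance or with either covariate, 2 without Day 7 in vitro replicate 2 or 3, Day 7 in vivo replicate 1 or 3 or Day 13 in vivo replicate 1. It was 3 without Day 13 in vitro replicate 3 or Day 13 in vivo replicate 2, and 5 without Day 7 in vivo replicate 2.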

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

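The tests with covariates for the poly-A spike-ins and the GAPDH 3' minus 5' difference, and the test of cumulus markers, were chosen only after the results they address were seen. The test of the interaction term was planned.

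What set the following results apart was that the change from Day 7 to Day 13 differed between embryos made in vitro and in vivo by a direct test of the difference, in 96 probe sets. The log2 difference of the change was 5.26 for CFI, 3.32 for TMEM38B, 3.26 for SLC12A2 and 2.58 for TMEM106C, and -8.90 for BEX4, -7.48 for BEX3, -6.21 for CD48, -5.83 for ADH6, -5.51 for DKK3, -4.67 for CYP51A1, -2.65 for FDFT1 and -2.64 for HMGCS1. The values of CFI, TMEM38B, SLC12A2, CD48, ADH6 and DKK3 rest on groups wholly at background, and with the background in their place were 4.14, 2.61, 3.69, -5.84, -4.72 and -4.03, of which only those of CD48 and DKK3 are bounds. Among gene lists the camera adjusted p was 8.72e-11 for ribosomal proteins (range 6.32e-13 to 0.593), 6.53e-10 for cholesterol biosynthesis (1.72e-10 to 0.0169), 0.00148 for cell cycle (9.75e-06 to 0.485), 0.0178 for oxidative phosphorylation (5.57e-05 to 0.987) and 0.0452 for ribosome biogenesis (0.00103 to 0.593). With an estimated correlation only cholesterol biosynthesis passed (0.0169), and 26 of 100 splits of the arrays gave as many lists, so chance is not excluded for those.

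Day 13 conceptuses of in vitro and in vivo origin differed in 288 probe sets, and the poly-A spike-ins separated the same arrays. With the GAPDH difference as a covariate the median of the log2 difference kept was 95.2% over the called probe sets and 89.6% over as many chosen by size. Of the 288, 138 still passed, with a median SE of 0.33 against 0.31. The GAPDH difference overlapped between these groups, 4.01 ± 1.01 (SD, n = 3) in vivo and 3.10 ± 0.92 in vitro, so that covariate could remove little. Those shares therefore do not exclude coverage along the transcript as a cause. With the poly-A mean as a covariate 76.0% was kept over the called probe sets, whose selection favours steady differences, and 8 of the 288 passed as the median size went from 2.16 to 1.60 and the median SE from 0.31 to 0.47. A set chosen by size, added after that value was seen, kept 41.6%, with a lower quartile of 13.1%, so amplification and labelling stay open for part or most of the difference. The hybridization spike-ins were lower in the same arrays too, 11.4 ± 0.79 in vitro and 13.2 ± 0.27 in vivo. The poly-A values therefore need not read amplification and labelling alone. A difference of origin between the embryos, of the sexes pooled or of the cell types recovered stays open too, and none was tested apart from the arrays.

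Cholesterol biosynthesis genes were higher in Day 7 blastocysts made in vitro. With the poly-A covariate the 15 members above background kept a median of 101% (median SE 0.36 against 0.33). With the GAPDH covariate they kept 89.2%, with a lower quartile of 67.4% and 12 members of the same sign (median SE 0.48 against 0.33). In each, 1 of 4 calls passed. Both slopes rest mostly on Day 13 arrays, where the SD within groups reached 1.87 (poly-A) and 1.01 (GAPDH), against at most 0.64 and 0.43 at Day 7. The Day 7 poly-A means, 14.7 in vivo and 14.1 in vitro, also lay close, so that covariate could remove little. Neither value therefore excludes labelling or coverage as a cause at Day 7. RNA from cumulus cells would raise their markers in vitro, and the median log2 difference of the 6 cumulus members above background on any array was -0.45 (quartiles -0.68 and -0.30), but FST lay below background on every Day 7 array and TNFAIP6 on most, so this value settles nothing. Of the 3 members above background on all arrays of a Day 7 group, HAS2 was 7.68 in vitro and 8.43 in vivo, STAR 4.73 and 5.85, and HSD3B1 7.65 and 7.24, which went both ways, so RNA from cumulus cells stays open. An effect of the way the blastocysts were made may also explain the difference, as a hypothesis found and tested on the same arrays. Culture, fertilization and parents were not separated by the design, and the sexes pooled were not tested apart from origin.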

How the results depend on the processing

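Counts of probe sets are given for the in vivo day, in vitro day, Day 7 origin, Day 13 origin and interaction comparisons in this order where all 5 moved. They were 1428, 2924, 81, 1118 and 269 with probe sets whose mean exceeded the median (775 shared between the day effects, 4 between the origin differences, 9 lists called in vivo), 1478, 2886, 81, 1215 and 278 with those above background on at least 3 arrays (shared 800 and 4). They were 564, 1129, 6, 100 and 20 with trended and robust variance (shared 290 and 0), 418, 748, 8, 80 and 43 with a test against 1.5-fold. They were 379, 702, 13, 75 and 39 at an adjusted p under 0.01, 604, 8237, 172, 2235 and 460 with array weights. They were 1582, 8795, 1391, 5725 and 3111 with weights from probe sets above background. Weights gene by gene gave 5884, 98, 1722 and 266, and both together 6164, 258, 3250 and 1347, for all but the in vivo day. On Day 7 in vitro replicate 1 the planned array weight was 12.6, and 35.2 with weights from probe sets above background. Both of these versions gave convergence warnings. Fits with only the groups compared gave 241, 787, 3 and 0 (limma, with 2178 at an unadjusted p under 0.05 in the last). A replicate term gave 568 in the in vivo day and 12, 119 and 47 in the last 3 (shared 297 and 0). Centring on ribosomal protein genes gave 1627 in the in vivo day, 727 at Day 13 and 215 in the interaction (shared origin 3). Centring on medians gave 477 at Day 13 and a filter at the 25th percentile 642 at Day 13 and 197 in the interaction (shared origin 2). Quantile normalization gave a shared origin count of 2 and 8 lists at Day 13. The GAPDH covariate gave 513 in the in vivo day, 14, 174 and 175 in the last 3 (shared 295 and 0) and 3 lists at Day 7. The poly-A covariate gave 199, 29, 9 and 12 in all but the in vivo day (shared 146 and 0). Leaving out Day 13 in vitro replicates 1 and 2 gave 902, 459 and 424 where they take part (shared day 270). Lists called with an estimated correlation were 1, 0, 1, 0 and 1, and with fry 14, 12, 5 and 9 in the first 4. With each array left out in turn the counts ranged over 676 to 923, 913 to 2898, 41 to 116, 135 to 2058 and 64 to 1083, shared day 308 to 501, shared origin 1 to 5, and lists 4 to 6, 3 to 7, 6 to 9, 1 to 6 and 3 to 8. Directions reversed with ribosomal centring for DLK1 (-0.0714), ITGB5 (-0.20) and RPL30 (-0.0106) in the in vivo day, with quantile normalization for ITGB5 (-0.0273). They reversed with another probe set for KAT2B in the in vivo day (0.052), NDUFB2 in the in vitro day (-1.22) and at Day 7 (0.79) and PLOD2 at Day 7 (-0.000946). With the GAPDH covariate they reversed for glycolysis in the in vivo day (adjusted p = 0.966) and at Day 7 (0.812) and oxidative phosphorylation at Day 7 (0.0675). Of the values for single genes and lists, 6309 kept their verdict at the threshold, 950 lost a call and 221 gained one. The 11 called in the main fit whose direction reversed are those just named. A change of size that did not cross the threshold, or of sign in a gene not called, counted as kept. Medians of lists under other scaling are not among these values, and those that turned are given with each list. The cause of these shifts was not tested, and probe sets near the background of 3.39 carry little signal.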

Other observations

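Between Day 13 conceptuses of the origins, markers of other cell types were not called as lists, apart from cumulus and granulosa markers (camera adjusted p = 0.0293, estimated correlation adjusted p = 0.237, range 0.00117 to 0.237). That call was lost without Day 13 in vitro or in vivo replicate 3 (adjusted p up to 0.17). The mean of the cumulus members above background rose from Day 7 to Day 13, from 5.21 to 7.43 in vivo and from 4.77 to 6.09 in vitro. The list therefore need not read RNA from cumulus cells. Endometrial epithelium (17 measured, 0 called), blood and immune cells (18 measured, 0 called) and fibroblasts and stroma (13 measured, 0 higher and 1 lower) had camera adjusted p of 0.211, 0.532 and 0.211, and endothelial and sperm lists 0.221 and 0.231. The mean of members above background, in vivo and in vitro (SD, n = 3), was 6.68 ± 0.31 and 5.57 ± 0.20 for endometrial epithelium. It was 5.11 ± 0.33 and 4.11 ± 0.08 for fibroblasts and stroma, and 4.99 ± 0.79 and 4.06 ± 0.50 for sperm. Blood and immune cells (3.05 ± 0.28 and 2.91 ± 0.01) and endothelium (3.99 ± 0.09 and 3.80 ± 0.21) differed less. Whether RNA from such cells adds to the difference between origins was not tested. Interferon-stimulated genes included 1 higher and 0 lower of 36 in that comparison (camera adjusted p = 0.395), beside an IFNT2 difference of 3.08 ± 0.84 that did not pass (n = 3 per group, adjusted p = 0.13). Maternal oocyte transcripts included 0 higher and 1 lower of 9 from Day 7 to Day 13 in vitro (camera adjusted p = 0.649).

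Metabolic and regulatory lists that did not pass in any comparison had members that did, except the pentose phosphate pathway. Genes of the TCA cycle included 0 higher and 2 lower of 22 in the in vivo day comparison (camera adjusted p = 0.0614) and the same counts in vitro (0.222). Chromatin genes included 1 higher and 2 lower of 22 in vivo, HDAC1 at -1.91 ± 0.21, with camera adjusted p of 0.27. Steroid synthesis genes included 2 higher of 17 in the in vitro day comparison (camera adjusted p = 0.963), amino acid transport 0 higher and 2 lower of 17 (0.963). Apoptosis had 1 higher and 2 lower of 19 (0.963), the pentose phosphate pathway 0 of 6 (0.551) and mesoderm genes 1 higher of 5 (0.139).

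Other groupings of the same arrays show how far chance can be excluded. For comparisons of 3 arrays with 3 the 10 splits are too few for a share under 0.05: the real split called 911 probe sets and 5 lists in vivo (highest other 7 and 4). It called 1804 and 7 in vitro (2 and 7), 50 and 9 at Day 7 (9 and 5), and 288 and 4 at Day 13 (51 and 5). The 1, 2 and 4 splits with a result as large, the real one included, are 1 for each count of probe sets and for the lists of the in vivo day and Day 7, 2 for the lists of the in vitro day and 4 for those of Day 13. For the interaction, 3 of 100 splits gave as many as 96 probe sets. One other split gave 322, which points to a structure of the samples, though its cause was not tested. The third gave 140 and exchanges the origins at Day 13 only, so it tests the sum of the origin differences and is not free of a real effect. For lists 26 of 100 gave as many as 5 lists (highest other 12), so chance is not excluded for those. For the shared day effect 1 of 100 splits, the real one, gave as many as 462 (highest other 0). At that level chance is excluded for a day effect. The other splits mix the days, and splits of that kind called at most 7 probe sets in vivo and 2 in vitro. A shared count near 0 follows from this, so these splits do not test whether the sharing between origins exceeds chance. For the shared origin difference 2 of 100 gave 1 or more (highest other 1), and a count of 1 that another split reached too says little.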
